A study of Homo sapiens with 10 samples.

How the data were processed

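RNA was measured by RNA sequencing in 10 human libraries. 4 were repeats of the Loucy cell line, which the labels list as early T cell precursor acute lymphoblastic leukemia (ETP-ALL). 3 were primary T cell acute lymphoblastic leukemias (T-ALL) and 3 were primary ETP-ALL. By the labels, each primary group held 2 bone marrow aspirates and 1 peripheral blood sample, the blood samples being T-ALL replicate 3 and ETP-ALL replicate 2. Per the labels' protocols, total RNA was extracted with a micro column kit, ribosomal RNA was depleted and libraries were made with the TruSeq protocol. The columns for Loucy carry the word DMSO in the deposited table, whereas the labels give no treatment, so these columns were matched to the Loucy group without a treatment. Loucy replicate numbers follow the order of these columns and may differ from the replicate numbers in the labels.

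The deposited table held TPM values (transcript abundance scaled to a fixed total per library) made by the authors, with 59611 genes listed by name and 1 column per library. Each column summed to 1000000 within rounding, as tested on the file. The submitters' processing notes name hg19, STAR 2.5.0c, Picard 2.6.0 and edgeR 3.14.0 without saying what each did. How reads were counted per gene, whether strand was used, the annotation and the gene lengths are not given in the sources used here. The deposited TPM values keep no record of library depth, so the depth is unknown and no counting interval or detection limit was computed. Of the genes listed, 15970 were at 0 in all libraries. No mitochondrially encoded gene was listed.

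Sex-linked transcripts were removed before any test (504 Y-linked and X-inactivation genes). Gene biotypes and transcript lengths came from GENCODE release 29, whose genome build differs from that in the submitters' notes. It gave a biotype to 54917 of the gene names, and no coordinate from it was used. TPM was transformed to log2(TPM + 1) without further scaling. A gene entered a comparison when it had a TPM of at least 1 in at least 3 of the libraries compared. Groups were compared with limma 3.58.1 (R 4.3.3), using empirical Bayes moderation with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The 3 comparisons were primary ETP-ALL minus primary T-ALL, Loucy minus primary ETP-ALL and Loucy minus primary T-ALL, each fitted on its own libraries. The comparisons with Loucy used array weights estimated per group, because repeats of a cell line vary less than donors. Their p-values therefore describe this line against these donors. Log2 fold changes are given ± standard error from limma and levels as mean TPM ± SD, with n = 3 for each primary group and n = 4 for Loucy.

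30 gene lists covering T cell stages, leukemia pathways, markers of other blood cell types and handling or quality genes were fixed before the data were examined, as were the comparisons, the tests and the alternatives not described as added later. A list was tested where at least 3 members entered the comparison. The main list test was limma's camera with a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it, and p-values were adjusted over all lists of a comparison. List medians are given relative to the median of all genes tested in that comparison. Gene counts are given with adjustment over all genes and adjusted over the list alone. The genes named were the 10 higher and 10 lower with the largest fold change among those past the threshold whose groups of libraries did not overlap, up to 4 members with the smallest p of each list called or described, and 36 fixed immunophenotype and transcription factor genes. Gene segments of the T cell receptor and immunoglobulin loci, HLA genes, genes with common germline deletions, small RNAs, clone-named transcripts and pseudogenes were not eligible to be named by this rule.

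Similarity of each primary sample to Loucy was Pearson's r across genes with the mean of the Loucy libraries, and the groups were compared with an exact two-sided permutation test. Concordance of comparisons that share libraries was set beside 50 simulations of unchanged groups. Tests on simulated data used 200 changed genes among the genes of each fit, with noise drawn from the gene-wise variances. At a log2 fold change of 2, 14 of 50 genes were called for ETP-ALL against T-ALL, 39 of 50 for Loucy against ETP-ALL and 38 of 50 for Loucy against T-ALL. The share of calls that were false was 14.1%, 46.7% and 30% for these comparisons in turn, above the nominal rate in each. A noise model with moderated variances, added after this was seen, gave 7.87%, 31.8% and 20.2%. These shares hold for 200 changed genes and are not estimates for the data, where the number of changed genes is unknown. With the gene-wise variances, 0.0573%, 0.514% and 0.278% of the unchanged genes were called. The counts with Loucy as a single sample, given with the alternatives, are the more cautious version of the Loucy comparisons for the genes that fit can test. A gene expressed in Loucy alone, such as HOXB9, cannot pass the filter there, which limits the higher counts.

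The alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter of TPM 5, median-centring, quantile normalization, rescaling without short, mitochondrial-like and histone genes, robust moderation, tissue as a covariate, marrow samples only, no array weights, other ways of entering Loucy in the fit, and leaving out each replicate in turn. Rescaling to protein-coding genes, and leaving out a donor with the genes of the full fit kept, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with tables handled in pandas 2.3.3.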

Results

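RNA levels were measured in 4 libraries of Loucy, a cell line derived from ETP-ALL. They were also measured in marrow or blood samples of 3 donors with T-ALL and 3 with ETP-ALL. ETP-ALL is a form of T-ALL whose cells resemble the earliest T cell progenitors in the thymus. The values were TPM as deposited. Their depth is unknown, and the number of genes above 0 ranged from 29715 to 31963 in Loucy, from 30287 to 32263 in ETP-ALL and from 26299 to 29079 in T-ALL. Genes are identified by the names in the table, which holds no coordinates. The Loucy libraries correlated with each other at Pearson's r of 0.970 to 0.978 across genes. A pair of abundant clone-named transcripts, singled out after the values were seen, took 15.2% ± 2.21 (SD, n = 4) of TPM in Loucy, 1.24% ± 0.78 (SD, n = 3) in ETP-ALL and 2.42% ± 0.777 (SD, n = 3) in T-ALL. Protein-coding genes held 73.9% ± 1.17, 78.4% ± 1.76 and 74.5% ± 6.41 of TPM in the same order. Entries named as nuclear copies of mitochondrial genes took 10.3% of TPM in T-ALL replicate 1 and at most 2.92% in every other library. As no mitochondrially encoded gene was listed, whether these entries hold reads of mitochondrial RNA is unknown.

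The comparison of primary ETP-ALL with primary T-ALL asked which transcripts separate the early subtype from other T-ALL. NOTCH3, a Notch receptor active in thymocytes, fell from 55.6 ± 18.9 TPM in T-ALL to 0.872 ± 0.606 in ETP-ALL, a log2 fold change of -4.92 ± 0.46 (n = 3 and 3). STAT3, a transcription factor downstream of cytokine receptors, rose from 41.1 ± 3.07 to 169.7 ± 28.1 TPM (2.01 ± 0.23). TRH, the precursor of thyrotropin-releasing hormone, rose by 4.70 ± 0.55 from levels near 0, while TSHR, the thyrotropin receptor, fell from 122 ± 79.5 to 3.27 ± 2.38 TPM (-4.79 ± 0.57). Other genes that rose were SHD (4.42 ± 0.43) and CLNK (3.64 ± 0.42), both adaptors of tyrosine kinase signalling, the cytoskeletal regulators ARHGAP42 (3.76 ± 0.46) and ACTN4 (2.53 ± 0.30), the trafficking protein gene ANKRD27 (2.23 ± 0.25), and KIAA1324L (3.82 ± 0.46). Genes that fell included RAPGEF5 (-4.78 ± 0.49), an activator of Rap GTPases, PAWR (-4.58 ± 0.55), a pro-apoptotic regulator, and GCSAM (-4.26 ± 0.46), a signalling adaptor of lymphocytes. BTG3 (from 93.1 to 4.78 TPM), an antiproliferative gene, TPD52 (-3.79 ± 0.41), PELI1 (-3.71 ± 0.36), a ubiquitin ligase, and FXYD2 (-3.70 ± 0.42), a regulator of the sodium pump, fell too. NUDT4B also fell (-4.08 ± 0.42), but it is a near copy of NUDT4 and its value is uncertain.

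Of 22868 genes tested with limma, 13 were higher and 21 lower in ETP-ALL, all at an adjusted p of 0.0456, and 3161 had an unadjusted p under 0.05. The 3 samples of each group did not overlap for 20.87% of genes, against 10% by chance. Genes are not independent replicates, and the median log2 fold change of all genes tested was 0.23, so the excess over 10% is not a test of the groups. These calls rested on few samples. With limma, no gene was called with a pseudocount of 0.1, with no filter, with tissue as a covariate or in marrow samples alone, where 2989, 3669, 2993 and 1492 genes had an unadjusted p under 0.05, and leaving out 1 sample gave between 0 and 3 higher and between 0 and 9 lower genes, of which at most 3 were among the 34.

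Genes of cortical thymocytes, the stage at which T cells rearrange their receptors, were lower in ETP-ALL. The list's median was -3.97 relative to all genes (camera adjusted p = 4.16e-16 over 17 genes, adjusted p = 0.0737 with an estimated correlation, fry adjusted p = 0.0196), and its mean log2 level was 6.52 ± 0.146 in T-ALL and 3.05 ± 0.709 in ETP-ALL. No member passed over all genes, and 11 fell when adjusted over the list alone. Among them CD1E was 2111 ± 1459 TPM in T-ALL and 14.0 ± 21.1 in ETP-ALL (-8.18 ± 1.18, adjusted p = 0.0634 over all genes and 0.000986 over the list). The lipid-presenting molecule gene CD1B (-7.37 ± 0.97), the pre-T cell receptor alpha chain gene PTCRA (-6.38 ± 0.94) and CD1A (-5.80 ± 0.84) had the same list-adjusted p. RAG1, an enzyme of receptor rearrangement, was at -3.80 ± 0.87 (adjusted p = 0.158).

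T cell receptor and CD3 signalling genes were lower as a list (median -1.03, camera adjusted p = 1.06e-06 over 20 genes, adjusted p = 0.503 with an estimated correlation). None passed over all genes and 2 fell when adjusted over the list alone, which were CD2 (-2.69 ± 0.40) and CD3E (-1.79 ± 0.40). SH2D1A (-1.32 ± 0.50) and CD28 (-2.22 ± 0.75) did not pass either test. Notch pathway genes were lower (median -1.33, camera adjusted p = 3.35e-05 over 10 genes, adjusted p = 0.503 with an estimated correlation). NOTCH3 passed over all genes and 3 members when adjusted over the list alone, among them PTCRA, which is also in the cortical list. In primary ETP-ALL against primary T-ALL with the same genes tested, the median was -2.19 without T-ALL replicate 3 (camera adjusted p = 2.69e-07). NOTCH1 itself was 62.6 ± 12.6 TPM in T-ALL and 88.1 ± 39.0 in ETP-ALL (0.39 ± 0.40, adjusted p = 0.691), and its target HES1 was at 0.54 ± 1.36.

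Stem and progenitor genes were higher in ETP-ALL (median 2.42, camera adjusted p = 4.34e-06 over 16 genes, adjusted p = 0.503 with an estimated correlation). No member passed over all genes, and 6 rose when adjusted over the list alone. Without ETP-ALL replicate 1, with the same genes tested in primary ETP-ALL against primary T-ALL, the median was 1.22 (camera adjusted p = 0.000109). CD34, the marker of blood progenitors, was 7.43 TPM on average in T-ALL and 222 in ETP-ALL (5.76 ± 1.08, adjusted p = 0.107 over all genes and 0.00403 over the list). In T-ALL it was 21.3 TPM in replicate 1 and 0.427 and 0.577 in the other samples. IGFBP7 (6.27 ± 1.06), MN1 (4.30 ± 0.77) and NPR3 (3.67 ± 0.52) had list-adjusted p of 0.00401, 0.00401 and 0.00312. Transcription factors of immature T-ALL were higher as a list (median 2.89, camera adjusted p = 4.34e-06 over 14 genes, adjusted p = 0.503 with an estimated correlation), with 0 passing over all genes and 7 rising when adjusted over the list alone. They included MYCN (5.39 ± 0.77), MEF2C (5.53 ± 1.06), LYL1 (3.10 ± 0.71) and NFE2 (4.29 ± 1.01). HHEX (4.69 ± 1.27), LMO2 (3.50 ± 0.88) and SPI1 (3.13 ± 0.81) were at list-adjusted p of 0.0152, 0.0139 and 0.0139. ZEB2 (2.82 ± 1.21) and BCL11A (0.00 ± 0.37) did not pass either test. T-ALL replicate 1 stood nearest to ETP-ALL in both lists, with mean log2 levels of 3.18 and 4.31, against at most 2.16 and 2.53 in the other T-ALL samples.

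Cell cycle genes were lower as a list in primary ETP-ALL against primary T-ALL (median -1.43, camera adjusted p = 2.94e-09 over 24 genes, adjusted p = 0.503 with an estimated correlation). All 24 estimates were negative, and no member passed over all genes or when adjusted over the list alone. MKI67 was at -2.21 ± 0.80, RRM2 at -2.48 ± 0.95, PCNA at -1.38 ± 0.55 and CCNE2 at -1.24 ± 0.49. The list's mean log2 level was 3.80 in ETP-ALL replicate 2, from blood, and 5.83 and 6.59 in the marrow samples of that group. Markers of NK and cytotoxic lymphocytes stood at 7.52 in that blood sample and at 5.27 and 4.78 in the marrow samples. Without it the cell cycle list was at -0.721 (camera adjusted p = 5.25e-05). Replication-dependent histone genes, a multigene family whose members can share reads, were lower (median -0.89, camera adjusted p = 0.000905 over 12 genes, adjusted p = 0.503 with an estimated correlation), with no member passing either test and H1-3 at -2.12 ± 0.86. That call ended in marrow samples alone (adjusted p = 0.0733) and with quantile normalization (adjusted p = 0.0693).

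NK and cytotoxic markers were higher in ETP-ALL as a list (median 1.41, camera adjusted p = 0.0221 over 13 genes, adjusted p = 0.75 with an estimated correlation), and no member passed either test. GZMB was at 2.73 ± 0.92, GZMA at 2.16 ± 1.04 and GNLY at 2.13 ± 1.10. The call ended without ETP-ALL replicate 2 (adjusted p = 0.434) and without T-ALL replicate 2 (adjusted p = 0.325). Interferon response genes were higher (median 1.40, camera adjusted p = 5.61e-05 over 18 genes, adjusted p = 0.522 with an estimated correlation). None passed over all genes and 2 rose when adjusted over the list alone, IFI44 (2.07 ± 0.48) and RSAD2 (2.38 ± 0.59), beside IRF7 (2.72 ± 0.76), which did not pass. The list's mean log2 level was 7.59 in ETP-ALL replicate 1 and 5.45 and 4.76 in the other ETP-ALL samples, and without replicate 1 the median was 0.625 (camera adjusted p = 0.0073).

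Cytokine receptor and JAK-STAT genes were higher (median 0.56, camera adjusted p = 0.0323 over 18 genes, adjusted p = 0.503 with an estimated correlation), with STAT3 the single member passing over all genes and when adjusted over the list alone. JAK3 (1.49 ± 0.44), JAK2 (0.98 ± 0.31) and STAT5A (2.01 ± 0.68) did not pass. Platelet and megakaryocyte markers were higher (median 0.81, camera adjusted p = 0.0273 over 5 genes, adjusted p = 0.503 with an estimated correlation, fry adjusted p = 0.043). None passed over all genes, and GP6, a collagen receptor of platelets, rose when adjusted over the list alone (2.71 ± 0.52). The platelet list's 10 members were low, with a mean log2 level of 1.33 ± 0.215 in ETP-ALL and 0.494 ± 0.339 in T-ALL. Both calls ended in marrow samples alone, with adjusted p of 0.352 and 0.167. Cytosolic ribosomal protein genes, which also form families with many copies, were lower (median -0.52, camera adjusted p = 0.00169 over 22 genes, adjusted p = 0.659 with an estimated correlation). No member passed either test, RPL5 was at -0.87 ± 0.41, and the call ended with quantile normalization (adjusted p = 0.576) and without ETP-ALL replicate 3 (adjusted p = 0.12).

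Apart from the cortical and platelet lists, the 10 lists called did not pass fry, with adjusted p from 0.0824 to 0.48. The remaining 15 lists tested were not called, with camera adjusted p from 0.0608 to 0.904. T-lineage transcription factors had a median log2 fold change of 0.19, which is -0.04 relative to all genes, and a mean of -0.22. Within that list TCF7 (-1.83 ± 0.31) and BCL11B (-2.26 ± 0.36), regulators of T cell commitment, were the 2 genes that fell when adjusted over the list alone (each at 0.00495), and GATA3 was at 0.35 ± 0.35. BCL2, an anti-apoptotic gene, rose when adjusted over its family alone (1.93 ± 0.42, adjusted p = 0.0166 over the list and 0.15 over all genes). The HOXA cluster varied within groups, and HOXA9 was 13.4 ± 15.6 TPM in T-ALL and 42.0 ± 36.3 in ETP-ALL (1.24 ± 1.87, adjusted p = 0.796). Of the remaining fixed genes, none passed over all genes: KIT was at 3.12 ± 1.46, CD33 at 2.89 ± 1.06, ANPEP at 2.62 ± 1.17, FLT3 at 2.25 ± 0.80 and ITGAM at 1.97 ± 1.10. CD7 was at 0.83 ± 0.37, CD5 at -1.55 ± 0.79, CD4 at -1.85 ± 0.80, CD8A at -1.82 ± 0.78, IL7R at -0.25 ± 0.82 and TAL1 at -1.89 ± 1.30. MPO, MEIS1, TLX1 and TLX3 did not enter the test. MPO averaged 57.8 ± 68.5 TPM in ETP-ALL and 0.276 ± 0.15 in T-ALL, and TLX3 was listed at 0 in all libraries. TLX1 averaged 58.5 ± 101 TPM in T-ALL, from 175 in replicate 3 and at most 0.15 in the other samples.

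**Figure D1:**
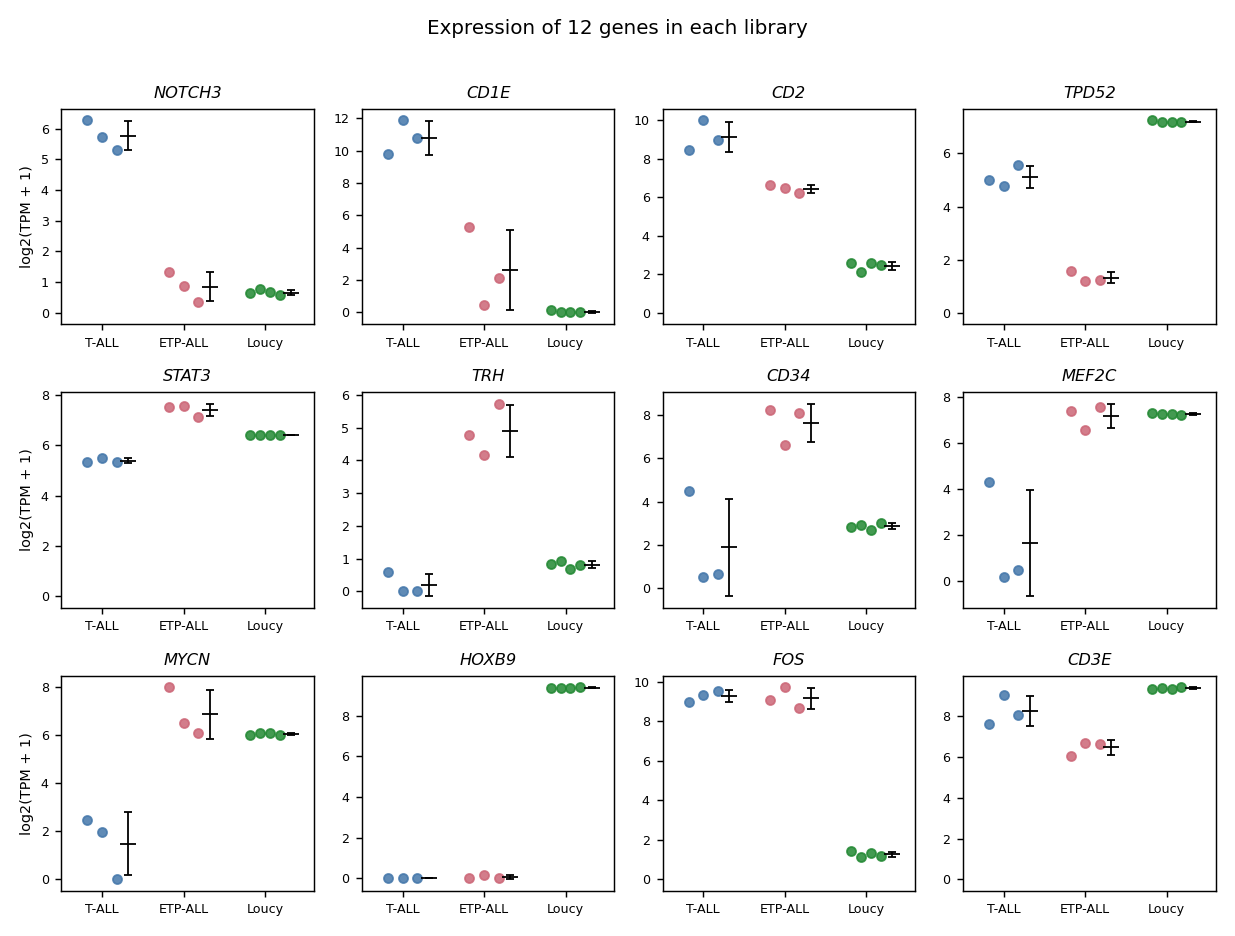
Level of 12 genes in each library as log2(TPM + 1), for T-ALL (n = 3), ETP-ALL (n = 3) and Loucy (n = 4); each point is a library and the bar is the group mean ± SD. NOTCH3 averaged 55.6 TPM in T-ALL, 0.872 in ETP-ALL and 0.576 in Loucy, while TPD52 was lowest in ETP-ALL (1.51 TPM) and highest in Loucy (146 TPM).

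Loucy was compared with primary ETP-ALL to ask where the cell line differs from primary samples of the subtype it stands for. Those are marrow and blood samples, so genes of other blood cells in them can appear as lower in Loucy. HOXB9 was 661 ± 12.6 TPM in Loucy and 0.041 ± 0.071 in ETP-ALL (log2 fold change 9.32 ± 0.12, n = 4 and 3), and HOXB8, its neighbour in the HOXB cluster, rose by 6.63 ± 0.22. FOS, an immediate early transcription factor, was 1.41 ± 0.205 TPM in Loucy and 594 ± 223 in ETP-ALL (-7.89 ± 0.27). CD34 fell to 6.29 ± 0.718 TPM from 222 ± 108 (-4.78 ± 0.36), and FLT3, a receptor of early progenitors, fell by 6.64 ± 0.55. The T cell gene CD3E was higher in Loucy (2.92 ± 0.15) and CD2 was lower (-4.02 ± 0.33). Further genes that rose were INHBE (7.08 ± 0.20), an inhibin subunit, the homeobox gene PITX1 (6.56 ± 0.45), TRIB3 (6.53 ± 0.34), a pseudokinase of the stress response, TMSB15A (6.36 ± 0.19), the histone variant gene MACROH2A2 (6.25 ± 0.30), XK (adjusted p = 0.00473), TPD52 (5.88 ± 0.16) and BCHE (5.81 ± 0.27). Genes that fell included AHR (-7.32 ± 0.31), the aryl hydrocarbon receptor, the chemokine gene CCL5 (-7.00 ± 0.46), TES (-6.93 ± 0.36), JCHAIN (-6.45 ± 0.59), a joining chain of antibodies, and NFKBIZ (-5.97 ± 0.30).

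With limma, 4205 genes were higher and 4318 lower in Loucy among 23954 tested. The Loucy libraries are repeats of 1 line. With their mean entered as 1 sample in a fit with the 6 primary samples, the counts were 101 and 418. Genes expressed in Loucy alone, such as HOXB9, cannot pass the filter of that fit, which limits its higher count. Leaving out 1 ETP-ALL sample with the same 23954 genes tested gave as few as 2342 higher and 1728 lower genes, both without replicate 1.

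Among the factors of immature T-ALL, MEF2C was 154 ± 3.63 TPM in Loucy and 150 ± 49.4 in ETP-ALL (0.10 ± 0.19, adjusted p = 0.727) and SPI1 was at 0.05 ± 0.36 (adjusted p = 0.931). LYL1 rose (1.41 ± 0.19), whereas LMO2 (-1.57 ± 0.27), ZEB2 (-2.10 ± 0.27) and BCL11A (-2.30 ± 0.29) fell, and HHEX was at 1.32 ± 0.45 (adjusted p = 0.0564). The list itself was not called (camera adjusted p = 0.101), nor were stem and progenitor genes (adjusted p = 0.0773, 3 up and 7 down over all genes, 3 up and 8 down when adjusted over the list alone). NOTCH1 (-2.91 ± 0.27), IL7R (-2.70 ± 0.57), TCF7 (-1.88 ± 0.15), CD8A (-3.36 ± 0.55), CD4 (-3.15 ± 0.66), KIT (-3.71, adjusted p = 0.0239, and -2.01 without ETP-ALL replicate 1 with the same genes tested, adjusted p = 0.0555), ANPEP (-3.41 ± 0.76), CD7 (-0.94 ± 0.27) and BCL2 (-0.73 ± 0.16) fell. GATA3 (0.88 ± 0.21), BCL11B (0.53 ± 0.17) and HOXA9 (3.21 ± 1.05) rose, and so did TLX1 (1.84 ± 0.30). For HOXA9, Loucy against primary ETP-ALL gave 1.26 without ETP-ALL replicate 3 (adjusted p = 0.00163) and did not pass without replicate 1 or replicate 2 (adjusted p = 0.0584 and 0.0532). Without replicate 2, CD7 (-0.59) and BCL11B (0.27) did not pass. No difference passed for CD5 (1.33 ± 0.50), CD1A (0.99 ± 0.42), CD33 (-1.31 ± 0.74), MPO (-2.43 ± 1.15), RAG1 (-1.29 ± 0.60), TAL1 (0.79 ± 0.47), ITGAM (-0.38 ± 0.62) or HES1 (-0.25 ± 0.28).

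Cell cycle genes were higher in Loucy (median 1.86, camera adjusted p = 1.79e-06 over 24 genes, adjusted p = 0.618 with an estimated correlation). 13 rose over all genes and 19 when adjusted over the list alone, and none fell. E2F1, which drives entry into S phase, rose from 5.71 ± 4.72 to 80.7 ± 1.39 TPM (3.85 ± 0.35), the mitotic kinase genes PLK1 (3.37 ± 0.34) and AURKB (3.22 ± 0.49) rose, and so did the replication licensing gene MCM2 (2.58 ± 0.38). Without ETP-ALL replicate 2, the sample low in these genes and high in cytotoxic markers, the median with the same genes tested in Loucy against primary ETP-ALL was 1.08 (camera adjusted p = 7.43e-07). Ribosome biogenesis genes were higher (median 0.70, camera adjusted p = 0.0011 over 17 genes, adjusted p = 0.581 with an estimated correlation), with 9 rising over all genes and 10 when adjusted over the list alone, among them RRP9 (3.45 ± 0.20), PES1 (1.71 ± 0.18) and NOLC1 (1.42 ± 0.17). Cytosolic ribosomal protein genes were lower (median -0.90, camera adjusted p = 1.1e-07 over 22 genes, adjusted p = 0.553 with an estimated correlation). 16 fell over all genes and 18 when adjusted over the list alone, including RPL13 (-2.36 ± 0.17) and RPS19 (-1.86 ± 0.12).

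Immediate early and stress genes were lower in Loucy (median -2.44, camera adjusted p = 1.79e-06 over 15 genes, adjusted p = 0.553 with an estimated correlation). 13 fell and 1 rose over all genes, with the same counts adjusted over the list alone, and FOSB (-6.88 ± 0.42), JUNB (-4.21 ± 0.26) and JUN (-3.76 ± 0.20) fell with FOS. Interferon response genes were lower (median -2.13, camera adjusted p = 0.00023 over 18 genes, adjusted p = 0.618 with an estimated correlation), with 13 down and 1 up over all genes and 15 down and 2 up when adjusted over the list alone. XAF1 (-5.88 ± 0.55), MX1 (-5.27 ± 0.59), RSAD2 (-3.97 ± 0.43) and IFI44 (-2.28 ± 0.28) fell, and without ETP-ALL replicate 1, with the same genes tested, the median was -1.51 (camera adjusted p = 0.000472). NK and cytotoxic markers were lower (median -3.75, camera adjusted p = 0.000273 over 12 genes, adjusted p = 0.618 with an estimated correlation), with 9 down over all genes and 9 down and 1 up when adjusted over the list alone. GNLY (-6.44 ± 0.66) and GZMB (-6.30 ± 0.40), which encode cytotoxic granule proteins, fell to averages below 0.1 TPM in Loucy. The list was drawn up as markers of other blood cells, but Loucy itself expressed some members, among them NKG7 (123 to 140 TPM) and CST7 (245 to 256 TPM). Whether other blood cells in the donor samples gave the difference was not tested. With the same genes tested in Loucy against primary ETP-ALL, this list was at -4.12 without ETP-ALL replicate 1 and at -3.12 without replicate 2 (camera adjusted p = 0.00328). MHC class II pathway genes were lower (median -3.04, camera adjusted p = 0.00886 over 7 genes, adjusted p = 0.618 with an estimated correlation). 5 fell over all genes and when adjusted over the list alone, and the invariant chain gene CD74 fell by 5.66 ± 0.64. The list's mean log2 level was 5.77 in ETP-ALL replicate 1 and 3.21 and 2.12 in the other ETP-ALL samples, and without replicate 1, with the same genes tested, the median was -2.24 (camera adjusted p = 0.00831). This call ended without array weights (adjusted p = 0.0755) and with the Loucy mean as 1 sample (adjusted p = 0.0535). Cortical thymocyte genes were lower (median -2.09, camera adjusted p = 0.0405 over 11 genes, adjusted p = 0.553 with an estimated correlation), with 6 down over all genes and 7 down and 1 up when adjusted over the list alone. ARPP21 (-3.00 ± 0.24) and CCR9 (-4.06 ± 0.77) were among those that fell. The cortical call ended in several alternatives, with adjusted p up to 0.168. The other 21 lists tested were not called, with camera adjusted p from 0.0773 to 0.921.

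Loucy was also compared with primary T-ALL, to set the distance of the cell line from the other subtype beside that of primary ETP-ALL. Here too, genes of other blood cells in the donor samples can appear as lower in Loucy. CD1E was 0.0208 ± 0.0415 TPM in Loucy and 2111 ± 1459 in T-ALL (-10.77 ± 0.35, n = 4 and 3), and CD1B (-10.10 ± 0.28), PTCRA (-7.91 ± 0.46), DNTT (-7.33 ± 0.26), which encodes terminal transferase, and RAG2 (-6.96 ± 0.36) fell as well. KLRF2, a lectin-like receptor of NK cells, was 708 ± 41.2 TPM in Loucy and 0.0667 ± 0.116 in T-ALL (9.38 ± 0.16). HOXB9, at 661 ± 12.6 TPM in Loucy, was listed at 0 in all 3 T-ALL samples. MEF2C (5.63 ± 0.72), MYCN (4.58 ± 0.43), LYL1 (4.51 ± 0.48) and HHEX (6.01 ± 0.78) rose, and NOTCH3 fell by 5.12 ± 0.32. Other genes that rose were RHEX (8.29 ± 0.33), a regulator of erythroid expansion, INHBE (7.38 ± 0.16), XK (7.10 ± 0.32), the succinate receptor gene SUCNR1 (6.81 ± 0.22), GCSAML (6.74 ± 0.58), CTH (6.69 ± 0.15), an enzyme of cysteine synthesis, PITX1 (6.53 ± 0.43) and TSPAN13 (6.49 ± 0.51). Other genes that fell were MAL (-8.11 ± 0.76), FOS (-8.00 ± 0.22), the peptidase gene DPP4 (-7.97 ± 0.41) and CD2 (-6.71 ± 0.38). ARPP21-AS1 fell too (-6.63 in log2), but it lies antisense to ARPP21 and the strand of counting is not known.

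With limma, 6080 genes were higher and 3813 lower in Loucy among 23234 tested. With the Loucy mean entered as 1 sample the counts were 288 and 591, and leaving out 1 T-ALL sample with the same 23234 genes tested gave as few as 2204 lower genes, without replicate 3. Here too, the filter of the fit with the Loucy mean leaves out genes expressed in Loucy alone.

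All 17 cortical thymocyte genes fell in Loucy, over all genes and when adjusted over the list alone (median -4.98, camera adjusted p = 1.92e-12), and this was the single list call that held with an estimated correlation (adjusted p = 0.0316). Notch pathway genes were lower (median -2.94, camera adjusted p = 0.000373 over 10 genes, adjusted p = 0.65 with an estimated correlation), with 7 falling over all genes and when adjusted over the list alone, among them NOTCH1 (-2.51 ± 0.17) and MYC (-5.32 ± 0.36). Myeloid progenitor genes were higher (median 2.28, camera adjusted p = 0.00826 over 6 genes, adjusted p = 0.252 with an estimated correlation), and 5 rose over all genes and when adjusted over the list alone. The list holds 16 genes, and those that did not enter included ELANE, PRTN3 and AZU1, at 0 in all Loucy libraries. A gene expressed in Loucy alone can pass the filter, as RAB44 did. CEBPB (3.86 ± 0.14) and CEBPE (3.32 ± 0.36), factors of myeloid differentiation, rose, as did MPO (1.41 ± 0.29), and RAB44 averaged 33.3 TPM in Loucy and listed at 0 in T-ALL. This call ended with no filter (adjusted p = 0.156). HOXA cluster genes were higher (median 2.21, camera adjusted p = 0.00833 over 11 genes, adjusted p = 0.74 with an estimated correlation), and 7 rose over all genes and when adjusted over the list alone, among them HOXA9 (4.46 ± 0.80) and HOXA11 (4.11 ± 0.33). In Loucy against primary T-ALL the HOXA call ended with the Loucy mean as 1 sample (adjusted p = 0.0883) and after rescaling to protein-coding genes (adjusted p = 0.0609).

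Cytosolic ribosomal protein genes were lower in Loucy than in T-ALL (median -1.53, camera adjusted p = 5.79e-13 over 22 genes, adjusted p = 0.252 with an estimated correlation). 19 fell over all genes and 20 when adjusted over the list alone, including RPL13 (-2.63 ± 0.13), RPS14 (-2.23 ± 0.09) and RPS23 (-2.13 ± 0.13). Ribosome biogenesis genes were higher (median 0.69, camera adjusted p = 0.0303 over 17 genes, adjusted p = 0.693 with an estimated correlation), with 11 up and 2 down by either count, a call that ended after rescaling to protein-coding genes (adjusted p = 0.311). Immediate early genes were lower (median -2.79, camera adjusted p = 1.09e-05 over 14 genes, adjusted p = 0.0783 with an estimated correlation), with 10 down and 1 up over all genes and when adjusted over the list alone, including FOSB (-6.56 ± 0.31), JUN (-4.56 ± 0.31) and DUSP1 (-4.48 ± 0.16). MHC class II genes (median -2.69, camera adjusted p = 0.0232 over 6 genes, adjusted p = 0.74 with an estimated correlation) had 4 down by either count, CD74 among them (-3.89 ± 0.69). Their mean log2 level was 4.27 in T-ALL replicate 1 and 1.46 and 2.44 in the other T-ALL samples. Without replicate 1, with the same genes tested in Loucy against primary T-ALL, the median was -2.04 (camera adjusted p = 0.0191), and the call ended without array weights (adjusted p = 0.0736) and with the Loucy mean as 1 sample (adjusted p = 0.115). Interferon response genes (median -0.91, camera adjusted p = 0.0308 over 17 genes, adjusted p = 0.65 with an estimated correlation) had 7 down and 3 up by either count. OAS2 (-4.30 ± 0.24), XAF1 (-4.17 ± 0.32) and MX1 (-3.86 ± 0.34) fell, and with the same genes tested the call ended without T-ALL replicate 1 (adjusted p = 0.0545) and without replicate 3 (adjusted p = 0.0874). NK and cytotoxic markers (median -2.64, camera adjusted p = 0.0393 over 12 genes, adjusted p = 0.754 with an estimated correlation) had 7 down and 2 up over all genes and 8 down and 2 up when adjusted over the list alone. GZMB (-3.57 ± 0.66) and GNLY (-4.31 ± 0.64) fell and PRF1 rose (2.21 ± 0.57), and with the same genes tested the call ended without T-ALL replicate 1 (median -2.15, adjusted p = 0.0767) and without replicate 3 (median -2.19, adjusted p = 0.0878). Histone genes (median -1.32, camera adjusted p = 0.0474 over 12 genes, adjusted p = 0.754 with an estimated correlation) had 5 down and 2 up by either count, with H3C2 (-4.11 ± 0.41) and H2AC6 (-3.26 ± 0.24) among those that fell, and this call ended with quantile normalization (adjusted p = 0.28).

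By fry, the cytotoxic and histone lists did not pass against T-ALL (adjusted p = 0.0602 and 0.0904). Cell cycle genes were not called against T-ALL (camera adjusted p = 0.0659), with 13 up and 3 down, nor were the other 17 lists tested, whose camera adjusted p ranged from 0.0658 to 0.968. Of the fixed genes, SPI1 (3.18 ± 0.50), LMO2 (1.92 ± 0.57), BCL2 (1.19 ± 0.25), GATA3 (1.24 ± 0.17), CD3E (1.13 ± 0.24), CD33 (1.58 ± 0.35) and ITGAM (1.59 ± 0.50) rose. FLT3 (-4.39 ± 0.47), CD8A (-5.18 ± 0.57), RAG1 (-5.09 ± 0.44), CD4 (-5.00 ± 0.40), CD1A (-4.81 ± 0.63), TCF7 (-3.71 ± 0.18), IL7R (-2.95 ± 0.13), BCL11A (-2.30 ± 0.20) and BCL11B (-1.73 ± 0.18) fell. Without T-ALL replicate 2 BCL2 was at 0.76 and ITGAM at 0.87, and without replicate 3 LMO2 was at 0.96, and of these BCL2 alone still passed. CD34 (0.98 ± 0.78), CD7 (-0.11 ± 0.17), CD5 (-0.23 ± 0.25), ZEB2 (0.72 ± 0.83), HES1 (0.29 ± 0.95), TAL1 (-1.10 ± 0.92) and TLX1 (-0.67 ± 1.35) did not pass.

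**Figure D2:**
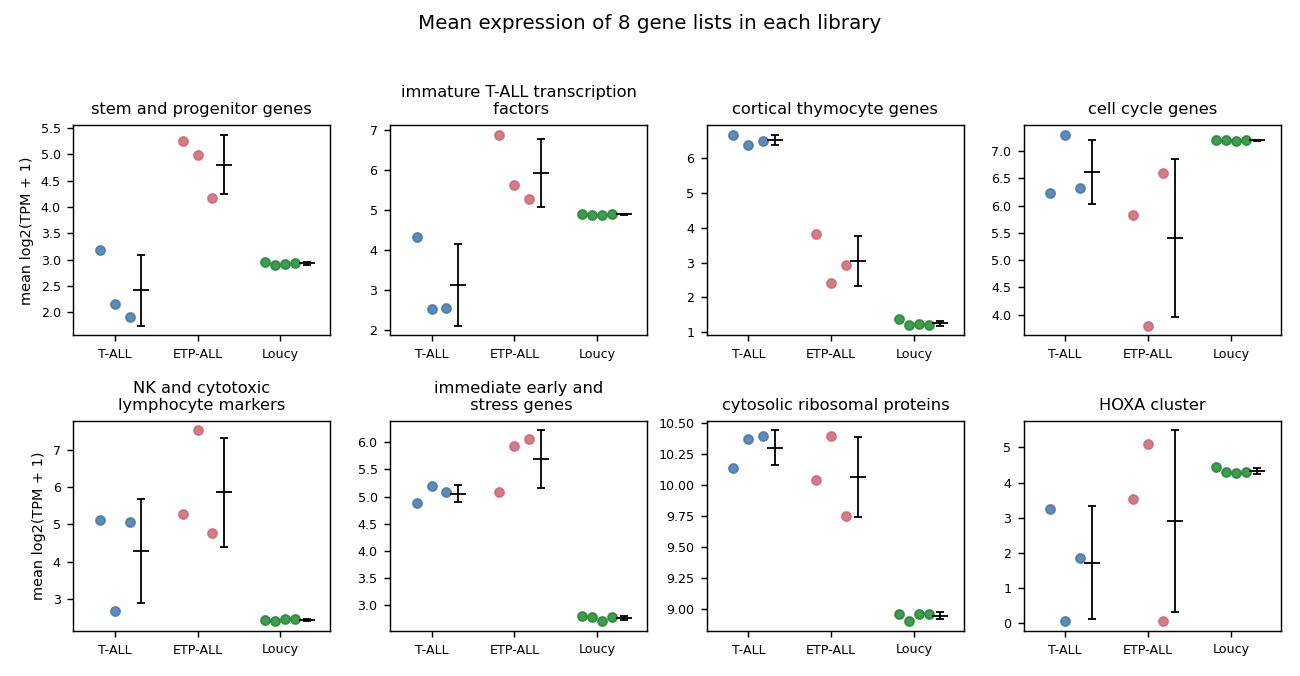
Mean log2(TPM + 1) of 8 gene lists in each library, for T-ALL (n = 3), ETP-ALL (n = 3) and Loucy (n = 4); each point is a library and the bar is the group mean ± SD. Cortical thymocyte genes averaged 6.52 in T-ALL, 3.05 in ETP-ALL and 1.26 in Loucy, and the ETP-ALL blood sample held the lowest cell cycle level (3.80) and the highest cytotoxic level (7.52).

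The similarity of the primary samples to Loucy was compared to ask which group the line lies closer to. Pearson's r with the Loucy mean, across 26112 genes that are not independent replicates, was 0.727 ± 0.00401 in ETP-ALL and 0.707 ± 0.0274 in T-ALL (SD, n = 3 each). The difference of 0.0205 did not exceed the spread between samples (exact two-sided permutation p = 0.4), and 3 samples against 3 cannot give less than 0.1. T-ALL replicate 2 had the highest value of the 6 samples (0.738). With Spearman's rho over the same 26112 genes the difference was 0.0266 (exact permutation p = 0.1). Over the 1000 genes most variable among the primary samples, the difference in Pearson's r was 0.115 (exact permutation p = 0.1).

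The change from T-ALL to ETP-ALL was then set against the change from T-ALL to Loucy. Across 20560 genes tested in both, log2 fold changes had a Pearson's r of 0.461 and a Spearman's rho of 0.422, and 64.38% of genes had the same sign. Genes are not independent replicates here, and both comparisons share the 3 T-ALL samples. All of these values lay below the averages in simulations of unchanged groups that share samples in the same way (0.653, 0.594 and 71.28%). They therefore do not show agreement, but they cannot exclude it, since changes in 1 comparison alone also lower them. The covariance of 0.705 lay above the average (0.166) and the highest (0.172) of the 50 simulations, so it exceeded what the shared samples gave there. 7 genes were higher and 17 lower in both comparisons, counts that the shared samples also raise. The 3 T-ALL samples are too few to be split between the comparisons. TPD52 was the 1 gene called in opposite directions, at -3.79 ± 0.41 in ETP-ALL and 2.09 ± 0.16 in Loucy. The pair of Loucy comparisons shared 3616 higher and 2411 lower genes, with 76 in opposite directions, and had an r of 0.833. The same line is in both, also when its libraries are divided between them (r of 0.808), so these values do not measure agreement of independent comparisons.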

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

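The tests reported here were chosen after the results were seen, except the first match on transcript length and abundance for the ribosomal protein genes and the alternatives other than the protein-coding rescaling and the leaving out of donors with the same genes tested. The 4 Loucy libraries were examined for a library standing apart from the others in 135 values, and 10 were found, where chance gives about 1 in 20. In 7 of them Loucy replicate 1 stood apart: its gap as a share of the group's range was 0.889 for entries named as nuclear copies of mitochondrial genes (0.233% of TPM in it), 0.922 for RAPGEF5, 0.845 for JAK2, 0.844 for CCNE2, 0.873 for CD8A, 0.84 for HOXA3 and 0.837 for MYC. Replicate 2 stood apart in PES1 (0.863) and JUNB (0.89), and replicate 3 in RRM2 (0.849). TPD52 moved in opposite directions from T-ALL in ETP-ALL and in Loucy, and the difference between them was 5.88 ± 0.16 in log2 (limma adjusted p = 3.83e-06).

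Other splits of the same libraries into groups of the same sizes were fitted with limma. For Loucy against ETP-ALL, 1 of 35 splits, the real one with 8523 genes, gave as many calls, and the highest other gave 0. For Loucy against T-ALL, 1 of 35 splits reached the 9893 genes called and the highest other gave 0. The 4 Loucy libraries are repeats of 1 line, so splits that mix them with donors call few genes by design, and 1 line against 3 donors is too few for a test of chance between samples. For ETP-ALL against T-ALL, 1 of 10 splits reached the 34 genes called and the highest other gave 1, and 10 splits are too few for such a test as well.

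Cell cycle genes were low in the ETP-ALL blood sample, with a median of -2.33 in log2 against the mean of the marrow samples (24 genes, SD 0.888), while NK and cytotoxic markers were higher there by 2.69 (13 genes, SD 1.03). Dilution of the leukemia cells by cytotoxic lymphocytes would lower the stem, progenitor and immature transcription factor genes alike. Their median was -0.346 (30 genes with a mean of at least 10 TPM, SD 1.59), a smaller fall than that of the cell cycle genes. Such genes also differ between donors, with stem and progenitor genes at mean log2 levels of 5.26 and 4.17 in the marrow samples. With blood from 1 donor, this cannot decide on dilution. In T-ALL the cell cycle genes of the blood sample had a median of -0.492 against the mean of the marrow samples (SD 0.651), but their mean level of 6.32 did not lie below both marrow samples (6.23 and 7.30). With 1 blood sample per group, tissue and donor cannot be told apart, and a difference in proliferation between donors stays open, untested.

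Ribosomal protein mRNAs were lower in Loucy than in either primary group, and medians here are not relative to all genes. Abundant noncoding transcripts that take up TPM in Loucy are argued against as the whole cause, since after rescaling to protein-coding genes the list's median log2 fold change was -0.941 against ETP-ALL (SD of the members 0.666) and -1.36 against T-ALL (SD 0.684), from -1.03 and -1.36 before. Transcript length is argued against, since 0% and 0% of 10000 lists matched on length and abundance had a median as low (median length 838 against 844 and 845), but these lists were less abundant, with median log2 levels of 9.13 and 9.16 against 9.62 and 9.74. Abundance is argued against by a closer match, with levels of 9.60 and 9.55 against 9.62 and 9.62 for the 22 and 20 members matched, in which 0% and 0% of lists had a median as low. The median of -1.03 against ETP-ALL may reflect culture or the line itself, and these cannot be told apart because no primary cells were cultured.

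Immediate early genes were lower in Loucy than in all 6 primary samples, by a median gap of 2.38 in mean log2 level. RNA from admixed blood cells is argued against, since the primary sample lowest in cytotoxic markers kept 1.02 of the median gap and the one lowest in monocyte and neutrophil markers kept 0.977. Handling of donor samples before lysis could raise these genes, and the gap of 2.38 fits that as well as a difference between the line and donor cells. Handling and origin are the same split of the samples and cannot be told apart.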

How the results depend on the processing

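All alternatives were planned except the protein-coding rescaling and the leaving out of donors with the same genes tested, and the cause was not tested for any change below unless stated. For ETP-ALL against T-ALL (13 higher, 21 lower), limma called 0 and 0 genes with a pseudocount of 0.1, with no filter (40673 genes tested), with tissue as a covariate and in marrow samples alone, at 2989, 3669, 2993 and 1492 genes with an unadjusted p under 0.05. It called 5 higher with median-centring, 7 higher after protein-coding rescaling, which tests fewer genes, and 1455 higher and 476 lower in one fit over all 10 samples, where the Loucy repeats enter the shared spread. Leaving out each replicate gave 0 to 3 higher and 0 to 9 lower genes, with 2247 to 3038 at an unadjusted p under 0.05, and the same ranges of called genes with the genes of the full fit kept.

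For Loucy against ETP-ALL (4205 higher, 4318 lower), the lower count was 2741 with a filter of TPM 5, 6792 without array weights and 1880 after protein-coding rescaling, and the Loucy mean as 1 sample gave 101 higher and 418 lower. With the Loucy mean as 1 sample, in both Loucy comparisons, genes expressed in Loucy alone cannot pass the filter. Leaving out each replicate gave 2347 to 4252 higher and 1133 to 4875 lower. The counts fell without ETP-ALL replicate 1 (2347 and 1133), replicate 2 (2798 and 1628) and replicate 3 (2319 lower). With a donor left out, genes under 1 TPM in all Loucy libraries cannot pass the filter, and with the genes of the full fit kept the counts were 2342 and 1728 without replicate 1, 2807 and 2387 without replicate 2, and 3814 and 3258 without replicate 3. For Loucy against T-ALL (6080 higher, 3813 lower), the lower count was 2459 with a filter of TPM 5 and 1757 after protein-coding rescaling, and the Loucy mean as 1 sample gave 288 higher and 591 lower. Leaving out each replicate gave 1430 to 4190 lower genes, with 1632, 1806 and 1430 without T-ALL replicates 1, 2 and 3, and 2455, 2651 and 2204 with the genes of the full fit kept.

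Pearson's r for the concordance of ETP-ALL minus T-ALL and Loucy minus T-ALL was 0.461, and 0.505 with a pseudocount of 0.1, 0.493 with a filter of TPM 5 and 0.413 to 0.504 on leaving out each replicate. The similarity to Loucy stayed higher in ETP-ALL by 0.0107 to 0.115 in its other settings.

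Scaling moved the median log2 fold change of all genes by -0.23 with median-centring and -0.20 with quantile normalization for ETP-ALL against T-ALL, by 0.13 and 0.18 for Loucy against ETP-ALL, and by -0.18 with median-centring for Loucy against T-ALL. Protein-coding rescaling changes both the scale and the genes tested, and moved it by 0.36 and 0.32 in the Loucy comparisons, while the median of the ribosomal protein genes moved from -1.03 to -0.941 and stayed at -1.36. Calls split 5 higher to 24 lower with median-centring for ETP-ALL against T-ALL, and 3564 to 1880 and 5069 to 1757 after protein-coding rescaling for Loucy against ETP-ALL and T-ALL. Median-centring gave 5371 to 5169 for Loucy against T-ALL.

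Reversed estimates belonged to genes not called, apart from the cytotoxic list. For ETP-ALL against T-ALL, BCL11A was 0.17 in marrow alone and NOTCH1 was -0.33 with the Loucy mean as an added ETP-ALL sample. SPI1 was -0.021 for Loucy against ETP-ALL after rescaling without short genes, and TLX1 was 0.77 for Loucy against T-ALL with a pseudocount of 0.1. Leaving out each replicate gave -0.39 to 0.24 for BCL11A (0.087 without T-ALL replicate 2, 0.145 without ETP-ALL replicate 3), -0.16 to 3.20 for HOXA9, -1.19 to 1.43 for HES1 and -0.84 to 0.79 for IL7R in ETP-ALL against T-ALL. It gave -0.602 to 0.003 for HES1, -1.27 to 0.64 for ITGAM, -0.21 to 0.29 for MEF2C and -0.42 to 0.53 for SPI1 in Loucy against ETP-ALL. It gave -2.74 to 0.74 for NK and cytotoxic lymphocyte markers, Loucy against primary T-ALL, a turn that was absent with the genes of the full fit kept (-3.59 to -2.15), and in that comparison -0.51 to 0.20 for CD5, -0.80 to 1.57 for ZEB2, -1.44 to 1.18 for HES1, -2.27 to 0.38 for TAL1 and -1.95 to 1.79 for TLX1, Loucy against primary T-ALL.

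Of the called lists, 7 of 12, 5 of 8 and 4 of 11 kept direction and call in all settings in which they were tested, for the comparisons in this order, and of the called named genes 0 of 18, 19 of 65 and 32 of 77. All of these settings kept camera's preset correlation of 0.01. With an estimated correlation, the cortical thymocyte list in Loucy against T-ALL was the single list call that held (camera adjusted p = 0.0316). No paired analysis was possible because the groups come from different donors and a cell line. Depth is unknown, so its limits cannot be given.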

Other observations

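The gene groups and genes here were chosen after their values were seen. Genes of the amino acid response, the programme that cells switch on when amino acids or protein folding are limiting, were higher in Loucy. All 32 members tested against ETP-ALL rose with limma, and 31 of 33 rose against T-ALL. The list medians relative to all genes were 3.45 and 3.35, with adjusted p = 0.0695 and adjusted p = 0.0558 with an estimated correlation. The mitochondrial folate enzyme gene SHMT2 was 731 ± 21.7 TPM in Loucy, 41.1 ± 14.7 in ETP-ALL and 32.5 ± 5.23 in T-ALL. MTHFD2 was on average 901 TPM in Loucy and 54.4 and 50.7 in the primary groups, and the stress sensor gene SESN2 was 203 ± 6.79, 5.33 ± 3.43 and 1.67 ± 0.657. ASNS, asparagine synthetase, a member of this programme, did not enter the tests. It stayed at 0.363 ± 0.143 TPM in Loucy and at 0.489 ± 0.137 and 0.371 ± 0.322 in the primary groups. ASNS was below 1 TPM in every library. Whether the annotation or the counting removed its reads is unknown, so these values do not show that it was unexpressed or unchanged. CHAC1 did not enter the Loucy comparisons, nor did ALDH1L2 against ETP-ALL, and both were below 1 TPM in all Loucy libraries. A member high in Loucy alone could enter. Between the primary groups no member of the list passed over all genes, and the list was not called (camera adjusted p = 0.125).

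HOXB cluster genes were higher in Loucy, with 7 of 8 rising against ETP-ALL and 8 of 8 against T-ALL (adjusted p = 0.431 and adjusted p = 0.123 with an estimated correlation). HOXB1 and HOXB13, at 0 in all Loucy libraries, did not enter the tests. A member high in Loucy alone, such as HOXB9, could enter, so these counts depend in part on the filter. HOXB7 was 67.2 ± 5.44 TPM in Loucy, 0.769 ± 1.33 in ETP-ALL and 0.032 ± 0.0554 in T-ALL. HOXB5 and HOXB6 were listed at 0 in all T-ALL samples, at 30.0 ± 4.49 and 39.9 ± 2.90 TPM in Loucy. Some of the cluster was also expressed in ETP-ALL replicate 2, at 13.3 TPM for HOXB5, 23.1 for HOXB6, 30.2 for HOXB4 and 82.0 for HOXB3, the last above the Loucy libraries (35.3 to 58.1). Polycomb and chromatin regulators were not called as a list against ETP-ALL or T-ALL (camera adjusted p = 0.407 and 0.705), with 3 up and 7 down in Loucy against the former and 5 up and 4 down against the latter. Of those that fell, EZH2, the methyltransferase of the Polycomb complex, was 6.02 ± 0.628 TPM in Loucy, 62.5 ± 16.4 in ETP-ALL and 128 ± 31.8 in T-ALL, and fell with limma by 3.15 and 4.17 in log2. TET2, a DNA demethylase gene, was 0.545 ± 0.0894 TPM in Loucy and 56.0 ± 44.9 and 27.7 ± 20.7 in the primary groups.

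Of 14 genes of the pseudoautosomal regions looked up, 11 were listed at 0 in all 10 libraries and the highest TPM of any was 0.705. Those at 0 included the widely expressed SLC25A6 and the list members CSF2RA, IL3RA and CRLF2, and whether the annotation or the counting removed these genes is unknown, so the zeros do not show that they were unexpressed.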
